A study of Homo sapiens with 6 samples.

How the data were processed

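Total RNA of T47D cells was extracted with a column kit, turned into sense-strand cDNA, fragmented and labelled with biotin for Affymetrix whole-transcript arrays, per the labels' protocols. There were 6 samples, 1 array each, with 3 in the vehicle group and 3 in the E2 group (10 nM for 6 h after 48 h of steroid depletion). Groups and replicate numbers were taken from the sample titles, which call the replicates biological.

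The authors deposited log2 signal values, 1 per probe set and array, with 2 decimals. Affymetrix Expression Console 1.1 and the PLIER algorithm are named per the submitters' processing notes, which give them no role or order, and how arrays were normalized to each other, the genome build and the annotation are not given in the sources used here. The authors deposited the log2 values as a table of 53427 probe sets and as a larger table that adds 190 control probe sets; the shared values were compared and 0 differed. That the scale is log2 was read from the values, and fold changes are those of the deposited log2 values. The groups share replicate numbers, but the labels do not say that a number marks a shared batch, so no pairing was used.

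Probe sets were named through a table of the platform's annotation. In it 23866 probe sets had 1 gene, 1852 had several and 27709 are unnamed here; 0 symbols needed updating. Genes were represented by probe sets with exactly 1 gene, and for the 630 genes with several the probe set with the highest mean over the 6 arrays was used, which gave 22392 genes. Older symbols in gene lists, neighbours and gene classes were matched through RefSeq gene names of the human assembly GRCh38.p14; no coordinates are printed, since no build is named for the arrays. Of 834 list entries 742 were measured, and the others were not analysed here.

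E2 and vehicle were compared gene by gene with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a trend of the prior variance on signal, without covariates or a filter on dim genes. Tests were two-sided, with Benjamini-Hochberg adjustment over 22392 genes and a threshold of 0.05. Each gene's variance had 10.4 degrees of freedom, of which 6.41 came from the prior. A single gene tested by exact permutation of 3 against 3 arrays cannot go below p = 0.1, so no such test was used. The design, the gene lists, the naming rule and most alternatives were set before the data were examined. The 37 lists were tested with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data and with fry, a rotation test of whether a list moves on balance one way by itself. With an estimated correlation camera also takes its degrees of freedom from the arrays, so its p can rise where the correlation does not. For the estrogen-induced list the estimate was -0.019, yet the unadjusted camera p went from 1.66e-66 to 3.38e-05. Counts of members are given over all genes and adjusted over the list alone. Lists overlap, so a gene can count in several.

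Genes were named by 3 rules. The first took 10 genes of estrogen response fixed in advance. The second took the 12 largest rises and 10 largest falls among genes past the threshold whose arrays separated the groups, without microRNA, small nucleolar and nuclear RNA, uncharacterized or pseudogene symbols. The third took, for each list, up to 4 members with the smallest p that passed, or 2 that did not where none passed. Where 5 or fewer members of a list rose or fell, the remaining ones were also named, a choice made after their values were seen.

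Alternatives were quantile normalization on top of the deposited values, equal array medians, an offset of 16 on the linear scale, leaving out the third of genes with mean log2 signal under 3.47, eBayes without a trend or with robust estimation, array weights, the mean of a gene's probe sets, the other table, the replicate number as a block, and each array left out. Array position, assumed from the number 5 or 7 that ends each array name, whose meaning is not given in the sources used here, was added after seeing the data, as a covariate and by keeping only the 4 arrays of position 5. Only E2 arrays have position 7, so in both forms the E2 effect is that of E2 replicate 1 over the vehicle arrays. Calls that end in these settings can reflect lost replication alone and do not show an effect of position. Figures were drawn with matplotlib 3.10.9.

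The test was first run on simulated data with the real genes' means, a spread fitted to their signal level, genes independent of each other and 200 of them changed. For E2 against vehicle over 22392 genes it recovered 10% of 50 genes changed by 0.3 on the log2 scale, 42% of those changed by 0.6, 92% of those changed by 1 and 100% of those changed by 2, with 7 calls among unchanged genes. With no gene changed it made 0 calls, and 0 lists passed. Since the simulated genes were independent, the list result does not show how often lists of correlated genes would pass without a change. Changes of about 0.3, recovered at 10%, were often missed in this simulation. In the data 1405 genes passed, so the unadjusted p needed to pass was less strict there, and recovery may have been higher.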

Results

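The data set held 6 expression arrays of T47D cells, an established line of estrogen receptor-positive luminal breast cancer cells. After 48 h in medium depleted of steroids, 3 cultures received ethanol, the vehicle, and 3 received 10 nM 17β-estradiol (E2), the main estrogen, for 6 h. The labels call the samples of each group biological replicates 1 to 3. The comparison of E2 with vehicle asks which transcripts change soon after the estrogen receptor is engaged, and the title of the series places it in the setting of cell metabolism. Array medians lay between 3.53 and 3.56 on the log2 scale, and the number of arrays limits the precision. Pairs of arrays correlated at 0.987 to 0.990 across the 53427 probe sets. The first principal component, 36.3% of the variance, separated the E2 from the vehicle arrays, and the second, 18.5%, placed E2 replicate 1 at -22.9 and E2 replicates 2 and 3 at 9.75 and 13.9. The array names end in a number that is 5 for the vehicle arrays and E2 replicate 1, and 7 for E2 replicates 2 and 3. It was taken as an array position, which is an assumption, since its meaning is not given in the sources used here.

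E2 changed the level of 1405 of 22392 genes, with 752 higher and 653 lower. Of the genes that rose, 679 code for proteins, and of those that fell, 610 do. Most changes were small, with a median of 0.47 on the log2 scale among the rises and 0.41 in size among the falls. At least 1.5-fold changes were found in 263 genes that rose and 155 that fell, and changes of at least 2-fold in 78 and 12. With an offset of 16 on the linear scale, which shrinks changes of dim genes, the 1.5-fold counts were 150 and 70. The test was limma's moderated test with Benjamini-Hochberg adjustment, at an adjusted p under 0.05. In all 1405 genes the 3 E2 arrays lay on one side of the 3 vehicle arrays. Such separation was seen in 4876 genes, 21.8% of those tested, where chance alone gives 10%. With array position as a covariate, or among the 4 arrays of position 5, the E2 effect rests on E2 replicate 1 alone. In both, the median ratio of the 1405 fold changes to those first obtained was 0.992. These arrays had also served to call the genes, so a high ratio is partly built in. For E2 replicate 1 over a vehicle array, both kept out of the call, median ratios were 0.839 to 0.897. Leaving out vehicle replicate 2 gave 906 genes, and leaving out E2 replicate 3 gave 892. Without a trend in the prior 578 passed, 346 higher and 232 lower. With equal array medians 687 were higher and 734 lower, so the balance of rises and falls depends on the scaling.

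**Figure D1:**
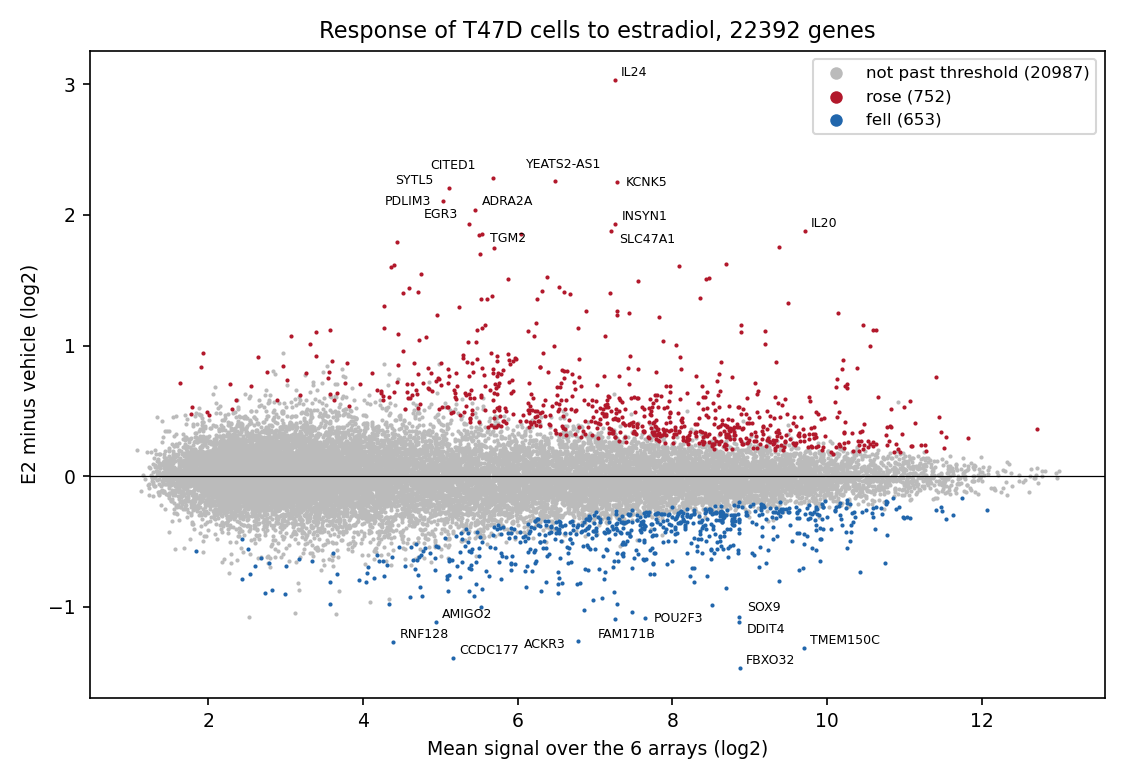
Change of each of the 22392 genes (E2 minus vehicle, log2, vertical axis) against its mean signal over the 6 arrays (log2, horizontal axis); red points rose (752), blue points fell (653) and grey points did not pass. The labelled genes are the 12 largest rises and 10 largest falls chosen by the naming rule, with IL24 at 3.03 and FBXO32 at -1.47 as the extremes.

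IL24, a secreted interleukin, rose most, from 5.74 ± 0.03 to 8.77 ± 0.02 (log2 mean ± SD, n = 3 arrays in each group), an 8.17-fold change with a 95% interval of 7.39 to 9.03 (adjusted p = 4.46e-09). IL20, the interleukin gene beside it on the chromosome, rose 3.66-fold. The transcriptional coactivator CITED1 rose 4.87-fold, the potassium channel KCNK5 4.77-fold and YEATS2-AS1, an antisense long noncoding RNA, 4.79-fold. SYTL5, a synaptotagmin-like protein, rose 4.61-fold, the actin-associated PDLIM3 4.31-fold and the adrenergic receptor ADRA2A 4.11-fold. EGR3, a zinc finger transcription factor, and INSYN1, an inhibitory synapse factor, each rose 3.80-fold, the organic cation exporter SLC47A1 3.67-fold and the transglutaminase TGM2 3.62-fold. The falls were smaller. FBXO32, the substrate-binding part of a ubiquitin ligase, went from 9.61 ± 0.10 to 8.14 ± 0.07 (SD, n = 3), a log2 change of -1.47 ± 0.07 (SE; adjusted p = 1.03e-06). CCDC177 changed by -1.39, TMEM150C by -1.31, the ubiquitin ligase RNF128 by -1.27, to an E2 mean of 3.76 near background that leaves the size uncertain, and ACKR3, an atypical receptor for CXCL12, by -1.26. DDIT4, an inhibitor of mTOR signalling, changed by -1.12, the adhesion protein AMIGO2 by -1.11, FAM171B and the transcription factor POU2F3 by -1.09, and SOX9, another transcription factor, by -1.08. The highest adjusted p among these 22 genes was 0.000492, for AMIGO2.

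Genes known to be induced by estrogen rose nearly as a block. Of 41 measured members of a list fixed from textbook knowledge, 39 rose and 0 fell, and the same list gave 40 rises adjusted over the list alone. ELOVL2, a fatty acid elongase, rose 3.07-fold, the chemokine CXCL12 3.05-fold, the transcription factor MYBL1 2.50-fold and the potassium channel KCNK5 4.77-fold. Among the genes named in advance, the receptor tyrosine kinase RET rose 3.36-fold, the scaffold protein PDZK1 2.84-fold, GREB1, an estrogen receptor cofactor, 2.38-fold and the secreted trefoil peptide TFF1 2.17-fold. The transcription factor MYC rose 1.53-fold, the progesterone receptor PGR 1.43-fold and cyclin D1, CCND1, 1.26-fold. The estrogen receptor gene itself, ESR1, measured 9.40 ± 0.106 with vehicle and 9.25 ± 0.105 with E2 (log2 mean ± SD, n = 3), a change of -0.15 ± 0.07 (SE) that did not pass (adjusted p = 0.319). Of 22 measured genes known to be repressed by estrogen, 13 fell and 0 rose, 17 fell adjusted over the list alone, and 8 fell among the 4 arrays of position 5. TP53INP1, a target of p53, changed by -0.86 ± 0.07, the interleukin receptor IL1R1 by -1.04 ± 0.09, the atypical cyclin CCNG2 by -0.71 ± 0.07 and the growth factor TGFB3 by -0.62 ± 0.06 (log2 ± SE). The lists shifted up and down by limma camera (adjusted p = 6.13e-65 and 5.62e-17), and with a correlation estimated from the data the adjusted p was 0.00125 and 0.0427. Among the 4 arrays of position 5 the CCND1 call ended (adjusted p = 0.0853), as it did without a trend in the prior (adjusted p = 0.0714).

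**Figure D2:**
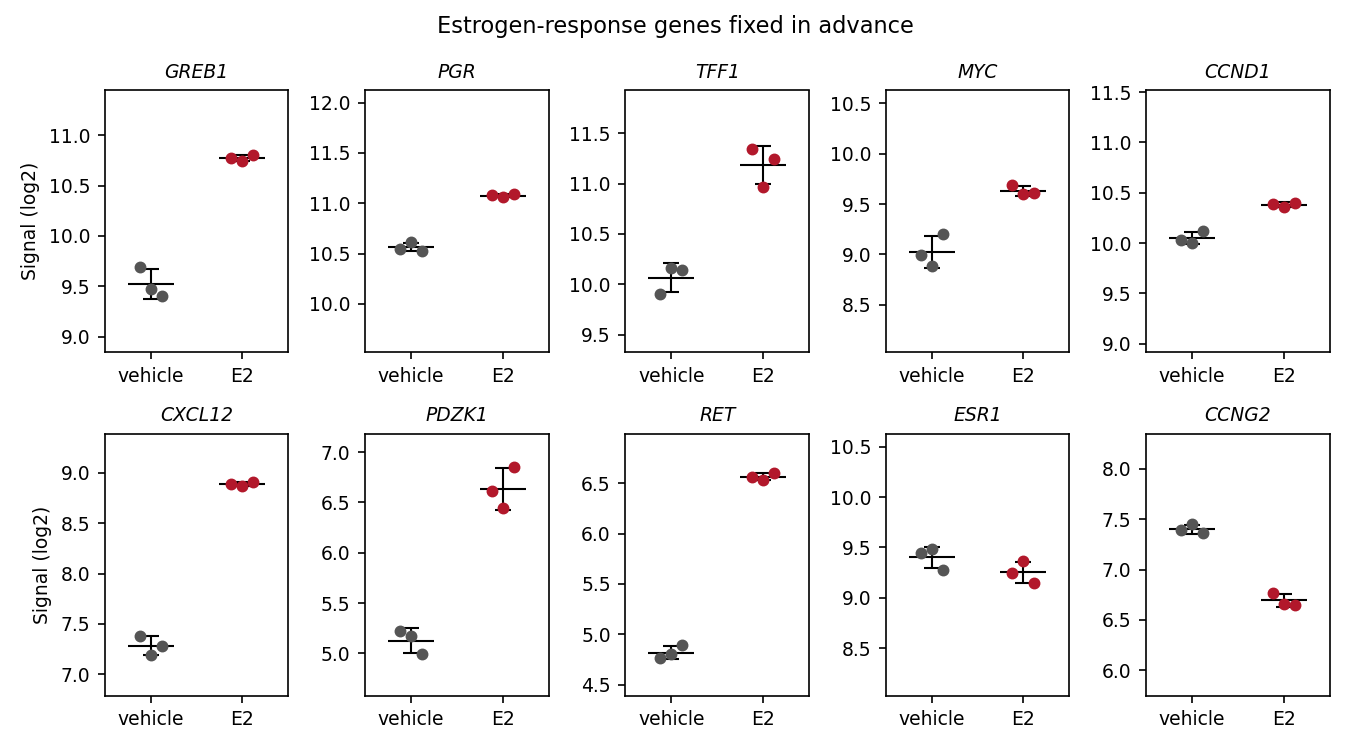
Signal (log2, vertical axis) of the 10 genes named in advance in the 3 vehicle arrays (grey) and the 3 E2 arrays (red); horizontal lines are group means, bars are 1 SD, and each panel spans the same range of log2 units. The arrays of the groups do not overlap for 9 of the genes, while those of ESR1 do.

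Single genes of glucose use changed. Of 20 measured glycolysis genes 2 rose and 0 fell, PFKFB3, which makes the activator of phosphofructokinase, by 0.73 ± 0.06 and the phosphofructokinase PFKP by 0.28 ± 0.07 (log2 ± SE, n = 3 in each group). The list did not pass (adjusted p = 0.0521), but did without vehicle replicate 2 (adjusted p = 0.0277) or by fry (adjusted p = 0.0225). The glucose transporter SLC2A1 was the 1 of 10 glucose and lactate transporters that rose, by 0.58 ± 0.07 (list adjusted p = 0.496). RPIA, ribose phosphate isomerase, was the 1 of 8 pentose phosphate genes that rose, by 0.35 ± 0.07 (list adjusted p = 0.879). Among 29 genes of pyruvate entry and the TCA cycle, PDHB, a subunit of pyruvate dehydrogenase, rose by 0.32 ± 0.06 and the mitochondrial pyruvate carrier MPC1 by 0.33 ± 0.07, while OGDH, of the oxoglutarate dehydrogenase complex, changed by -0.26 ± 0.07 (list adjusted p = 0.892). Of 34 nuclear genes of oxidative phosphorylation, cytochrome c, CYCS, rose by 0.44 ± 0.10 and 33 did not pass (list adjusted p = 0.227). The 21 genes of mitochondrial biogenesis shifted up as a list (adjusted p = 0.00165; adjusted p = 0.088 with an estimated correlation). In it the mitochondrial helicase TWNK, by 0.62 ± 0.09, and the coactivator PPARGC1B, by 0.65 ± 0.16, rose, 7 members rose adjusted over the list alone, and 1 fell by that count. Adjusted over each list alone, the calls were 2 rises in glycolysis, 2 rises and 2 falls among the transporters, 1 rise in the pentose phosphate list, 2 rises and 1 fall around the TCA cycle and 0 in oxidative phosphorylation, where 1 gene passed over all genes. The calls of PFKP and CYCS ended with any array other than vehicle replicate 3 left out, that of PPARGC1B with any other than vehicle replicate 1 and that of OGDH with any other than E2 replicate 1. That of RPIA ended without vehicle replicate 2 or E2 replicate 2 and that of MPC1 without vehicle replicate 2 or 3 or E2 replicate 2 or 3 (adjusted p up to 0.154 over these genes). Of the genes named here only PFKFB3, SLC2A1 and TWNK kept their calls with array position as a covariate (adjusted p of the others 0.083 to 0.504), and PFKP, RPIA, PDHB, MPC1, OGDH and PPARGC1B also lost theirs without a trend in the prior (adjusted p = 0.0773 to 0.213).

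Lipid genes moved in both directions. Of 20 measured genes of fatty acid synthesis 4 rose and 1 fell, both over all genes and adjusted over the list alone. ELOVL2 rose by 1.62 ± 0.05 (log2 ± SE, n = 3 in each group), THRSP, a regulator of lipogenesis, by 1.04 ± 0.17, and the elongases ELOVL6 and ELOVL5 by 0.30 ± 0.07 and 0.21 ± 0.05. SREBF1, the transcription factor that drives lipogenic genes, changed by -0.39 ± 0.06. The list did not pass by camera (adjusted p = 0.878) but did by fry (adjusted p = 0.0283), and its median of -0.05 and mean of 0.09 differ in sign. Of 19 genes of fatty acid oxidation 2 fell and 0 rose, as they did adjusted over the list alone. These were CPT1A, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, by -0.24 ± 0.05 and the thiolase ACAA2 by -0.23 ± 0.05. That list shifted down (adjusted p = 0.0176), but not with an estimated correlation (adjusted p = 0.253). Nor did it with array position as a covariate (adjusted p = 0.0663), among the arrays of position 5 (adjusted p = 0.0764), without vehicle replicate 2 (adjusted p = 0.0954), without the dimmest genes (adjusted p = 0.054) or without a trend (adjusted p = 0.0554). Of 18 cholesterol synthesis genes, HMGCS1, which makes hydroxymethylglutaryl-CoA, rose by 0.39 ± 0.06 and the sterol desaturase SC5D changed by -0.27 ± 0.06. Adjusted over that list alone 2 rose and 1 fell. The list did not pass (adjusted p = 0.0521), but did without vehicle replicate 2 (adjusted p = 0.0289), without E2 replicate 1 (adjusted p = 0.0415) or with array weights (adjusted p = 0.0489). The calls of ELOVL5 (any array), ELOVL6 (any array other than E2 replicate 1), ACAA2 (vehicle replicate 2 or 3, or E2 replicate 1 or 3) and SC5D (vehicle replicate 2, or E2 replicate 2 or 3) ended with the arrays in parentheses left out (adjusted p up to 0.154). ELOVL2 alone of these genes kept its call with array position as a covariate (adjusted p of the others 0.0626 to 0.299). The calls of SREBF1, ELOVL6, ELOVL5, CPT1A, ACAA2, HMGCS1 and SC5D ended without a trend in the prior (adjusted p = 0.0529 to 0.201).

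Lists of genes for one-carbon units and nucleotides shifted up, and so did amino acid transporters, but not with an estimated correlation (adjusted p = 0.176 with an estimated correlation). Of 19 amino acid transporters 6 rose and 2 fell, and 8 rose and 3 fell adjusted over the list alone. The cationic amino acid transporter SLC7A2 rose by 1.01 ± 0.06 (log2 ± SE, n = 3 in each group), and SLC7A5 and SLC3A2, which form a transporter of large neutral amino acids, by 0.36 ± 0.04 and 0.32 ± 0.05. SLC7A8 and SLC43A2, other carriers of neutral amino acids, changed by -0.32 ± 0.07 and -0.22 ± 0.05. The adjusted p of this list was 0.00489. Of 20 genes of glutamine, serine, one-carbon and polyamine metabolism 8 rose and 0 fell, and 10 rose adjusted over the list alone (list adjusted p = 1.22e-06; adjusted p = 0.0427 with an estimated correlation). Examples were AMD1 of polyamine synthesis with 0.56 ± 0.05, the mitochondrial folate enzyme MTHFD1L with 0.51 ± 0.07, the serine synthesis enzyme PSAT1 with 0.35 ± 0.06 and thymidylate synthase, TYMS, with 0.27 ± 0.05. Of 18 nucleotide synthesis genes 5 rose and 0 fell, and 8 rose adjusted over the list alone (list adjusted p = 2.73e-05; adjusted p = 0.0427 with an estimated correlation). Besides TYMS these were CTP synthase CTPS1 with 0.45 ± 0.07, the pyrimidine enzymes DHODH with 0.43 ± 0.07 and UMPS with 0.32 ± 0.05, and the purine enzyme ADSL with 0.30 ± 0.07. The calls of SLC7A8, SLC43A2 and ADSL ended without vehicle replicate 1 or 2 or E2 replicate 2 or 3 (adjusted p up to 0.0915). With array position as a covariate the calls of SLC7A8, SLC43A2, PSAT1, TYMS, CTPS1, UMPS and ADSL ended (adjusted p = 0.0534 to 0.291), and among the arrays of position 5 also those of SLC3A2 and DHODH (adjusted p = 0.0623 and 0.058). Without a trend in the prior those of SLC7A5, SLC3A2, SLC7A8, SLC43A2, PSAT1, TYMS, UMPS and ADSL ended (adjusted p = 0.0526 to 0.181).

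The counts of rises in these lists moved with the settings. The 6 rises among amino acid transporters became 3 without vehicle replicate 2 or without E2 replicate 2, while the 2 falls became 0 without vehicle replicate 1 or 2 or E2 replicate 2 or 3. The 8 rises among genes of glutamine, serine, one-carbon and polyamine metabolism became 5 without vehicle replicate 1, vehicle replicate 2 or E2 replicate 3, and 4 without E2 replicate 2. Among the amino acid transporters, the one-carbon genes and the nucleotide synthesis genes 3, 2 and 1 rose with array position as a covariate. It was 2, 2 and 0 among the arrays of position 5, and 1, 2 and 2 without a trend. The lists still shifted up with that covariate (adjusted p = 0.0166, 6.42e-05 and 0.00183).

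**Figure D3:**
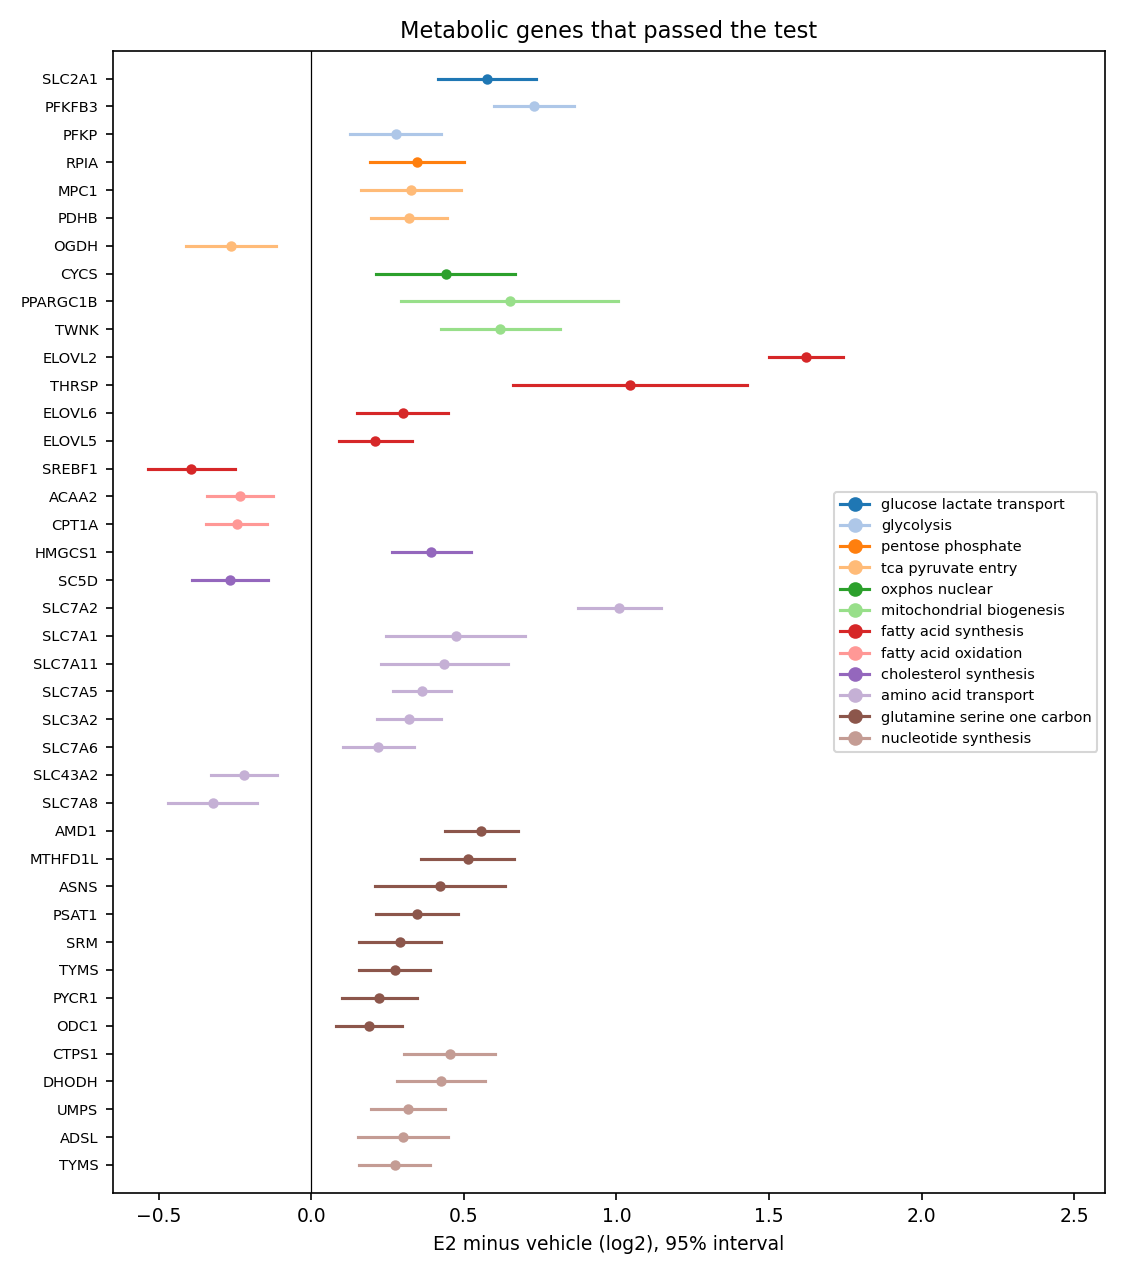
Change (E2 minus vehicle, log2, horizontal axis) of the 39 genes of 12 metabolic lists that passed the test, coloured by list, with TYMS shown in both of its lists; points are estimates from 3 arrays in each group and bars their 95% intervals. SLC7A2, ELOVL2 and THRSP lie above 1, and the falls range from SLC43A2 at -0.22 to SREBF1 at -0.39.

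Most genes of ribosome biogenesis rose. Of 35 measured members 24 rose and 0 fell, and 31 rose adjusted over the list alone (list adjusted p = 6.04e-26; adjusted p = 0.00433 with an estimated correlation). The 24 rises became 13 with array position as a covariate, 6 among the arrays of position 5 and 14 without a trend in the prior, and the list still shifted up with that covariate (adjusted p = 3.44e-20). The assembly factors RRS1, BOP1, BYSL and NIP7 rose by 0.60 ± 0.06, 0.53 ± 0.06, 0.52 ± 0.06 and 0.44 ± 0.06 (log2 ± SE, n = 3 in each group). Of 19 tRNA synthetases 4 rose and 0 fell, each by a small amount, YARS1 with 0.33 ± 0.07, GARS1 with 0.26 ± 0.06, FARSA with 0.23 ± 0.06 and FARSB with 0.18 ± 0.04. Adjusted over the list alone 6 rose and 1 fell (list adjusted p = 2.73e-05; adjusted p = 0.148 with an estimated correlation). Of 14 chaperones 4 rose and 0 fell, and 6 rose adjusted over the list alone (list adjusted p = 2.56e-05; adjusted p = 0.0427 with an estimated correlation). They were the small heat shock protein HSPB8 with 1.16 ± 0.12, the immunophilin FKBP4 with 0.61 ± 0.06, DNAJA1 with 0.41 ± 0.06 and HSPH1 with 0.23 ± 0.05, and the first pair also belong to the estrogen-induced list. In the unfolded protein response, XBP1, its transcription factor, rose by 0.30 ± 0.05 and SDF2L1 by 0.27 ± 0.07, 21 of 23 genes did not pass, and 4 rose and 1 fell adjusted over the list alone (list adjusted p = 0.1, and 0.0254 by fry). The calls of FARSB and SDF2L1 ended with any array left out, and those of FARSA and HSPH1 with any other than E2 replicate 1. That of YARS1 ended without vehicle replicate 2 or 3 or E2 replicate 1 or 2, and that of GARS1 without vehicle replicate 1 or 3 or E2 replicate 1 or 2 (adjusted p up to 0.15). RRS1, BOP1, BYSL, NIP7, FKBP4 and HSPB8 kept their calls with array position as a covariate, and the others here did not (adjusted p = 0.0523 to 0.454), nor did they without a trend (adjusted p = 0.0563 to 0.244).

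Genes of G1/S transition and DNA replication shifted up as a list. Of 40 measured members 14 rose and 0 fell, 26 rose adjusted over the list alone, and 39 had a positive estimate (list adjusted p = 6.29e-17; adjusted p = 0.0065 with an estimated correlation). The 14 rises became 9 without vehicle replicate 2 or without E2 replicate 2, 8 without E2 replicate 1 or without E2 replicate 3, 3 with array position as a covariate, 0 among the arrays of position 5 and 1 without a trend in the prior. The list still shifted up in each of these, at position 5 with an adjusted p of 5.03e-11. The phosphatase CDC25A rose by 0.50 ± 0.07 (log2 ± SE, n = 3 in each group), CCND1 by 0.33 ± 0.05, the origin licensing factor CDC6 by 0.54 ± 0.09 and the helicase subunit MCM6 by 0.32 ± 0.06. Of 28 genes of G2/M and mitosis 2 fell and 0 rose, the kinesin KIF20A with -0.43 ± 0.06 and the phosphatase CDC25C with -0.33 ± 0.08, and 5 fell adjusted over the list alone (list adjusted p = 0.00195; adjusted p = 0.124 with an estimated correlation). Of 21 cyclin-dependent kinase inhibitors and other antiproliferative genes 7 fell and 1 rose, and 8 fell and 3 rose adjusted over the list alone (list adjusted p = 0.00233; adjusted p = 0.089 with an estimated correlation). The 7 falls became 4 among the arrays of position 5. TP53INP1, CCNG2 and the pocket protein RBL2, with -0.54 ± 0.06, fell, and the stress gene GADD45B rose by 0.69 ± 0.06. Apoptosis genes went both ways (list adjusted p = 0.395, and 0.0383 by fry), with 2 rises and 3 falls among 24, and 2 rises and 5 falls adjusted over the list alone. The antiapoptotic BCL2 rose by 0.62 ± 0.06 and the proapoptotic PMAIP1 by 0.88 ± 0.13, while the death ligand TNFSF10 changed by -0.65 ± 0.05 and the proapoptotic BIK and BMF by -0.76 ± 0.12 and -0.57 ± 0.12. The call of CDC25C ended without vehicle replicate 2 or 3 or E2 replicate 2 or 3, and that of BMF without vehicle replicate 1 or 3 or E2 replicate 2 (adjusted p up to 0.128). With array position as a covariate the calls of CDC6, MCM6, KIF20A, CDC25C and BMF ended (adjusted p = 0.0727 to 0.306), and among the arrays of position 5 also those of CDC25A and CCND1 (adjusted p = 0.0533 and 0.0853). CCND1, CDC6, MCM6, KIF20A and CDC25C lost theirs without a trend (adjusted p = 0.0522 to 0.105).

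Among signalling genes the joint list of TGFβ, Wnt and Notch components shifted down, with 11 of 27 lower and 1 higher, and 12 lower and 2 higher adjusted over the list alone (list adjusted p = 0.000216; adjusted p = 0.0486 with an estimated correlation). The pathways were not tested apart, and TGFB3, SMAD6 and HES1 also belong to the estrogen-repressed list. The 11 falls became 6 without vehicle replicate 1, 7 without vehicle replicate 3, E2 replicate 1 or E2 replicate 3, 3 with array position as a covariate, 1 among the arrays of position 5 and 4 without a trend in the prior. The list still shifted down with that covariate (adjusted p = 0.00447) and at position 5 (adjusted p = 0.00378). TGFB3, with -0.62 ± 0.06, the inhibitory SMAD6, with -0.62 ± 0.10, and the receptor NOTCH3, with -0.59 ± 0.09, fell (log2 ± SE, n = 3 in each group), whereas HEY2, a Notch target, rose by 1.85 ± 0.09. Of 26 immediate early genes 5 rose and 3 fell, and 9 rose and 3 fell adjusted over the list alone. EGR3 rose by 1.93 ± 0.18, FOS by 0.90 ± 0.11, MYC by 0.61 ± 0.08, SPRY2 by 0.51 ± 0.13 and IER3 by 0.22 ± 0.05, while SPRY1 changed by -0.70 ± 0.12, DUSP5 by -0.47 ± 0.09 and JUNB by -0.43 ± 0.06. The list shifted up (adjusted p = 0.0164), but not with an estimated correlation (adjusted p = 0.124), with array position as a covariate (adjusted p = 0.0572), among the arrays of position 5 (adjusted p = 0.0764) or without vehicle replicate 2 (adjusted p = 0.06). Of 25 growth factor and receptor genes 6 rose and 3 fell, and 7 rose and 5 fell adjusted over the list alone (list adjusted p = 0.0521), while among the arrays of position 5 it was 2 and 1, and without a trend 4 and 1. That list passed without vehicle replicate 1 (adjusted p = 0.0367), without E2 replicate 3 (adjusted p = 0.0481), with quantile normalization (adjusted p = 0.0475), with array weights (adjusted p = 0.0489) and by fry (adjusted p = 0.00114). RET rose by 1.75 ± 0.09, the insulin receptor substrate IRS2 by 0.80 ± 0.10 and the binding protein IGFBP4 by 0.76 ± 0.06, and the receptors ERBB3, ERBB4 and FGFR4 changed by -0.49 ± 0.06, -0.46 ± 0.07 and -0.42 ± 0.08. The calls of IER3 (vehicle replicate 1 or 2, or E2 replicate 2 or 3) and SPRY2 (any array other than E2 replicate 1) ended with the arrays in parentheses left out (adjusted p up to 0.14). With array position as a covariate NOTCH3, IER3, SPRY2, SPRY1, DUSP5 and FGFR4 lost theirs (adjusted p = 0.0766 to 0.341), and among the arrays of position 5 also SMAD6, JUNB, IRS2 and ERBB3 (adjusted p = 0.0533 to 0.095). Those of IER3, SPRY2, DUSP5, ERBB4 and FGFR4 ended without a trend (adjusted p = 0.0534 to 0.207).

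The other signalling and stress lists did not pass by limma camera. Among 23 nuclear receptors and coregulators CITED1, NRIP1 (1.11 ± 0.07), RARA (0.82 ± 0.09), TFAP2C (0.61 ± 0.06) and PGR rose, and RXRA (-0.40 ± 0.06) and GATA3 (-0.23 ± 0.04) fell (log2 ± SE, n = 3 in each group). In that list 5 rose and 4 fell adjusted over the list alone, and the median of -0.12 and mean of 0.14 differ in sign (list adjusted p = 0.878). Of 16 ion channel and calcium genes 4 rose, KCNK5, KCNK6 (0.54 ± 0.06), KCNF1 (0.49 ± 0.12) and CALCR (0.47 ± 0.10), and CACNA1D (-0.34 ± 0.06) fell. Adjusted over the list alone 4 rose and 3 fell, and the median of -0.04 and mean of 0.17 differ in sign (list adjusted p = 0.445). By fry this list passed (adjusted p = 0.000132). Of 18 hypoxia genes 5 rose, STC2 (0.83 ± 0.07), SLC2A1, ADM (0.42), CA12 (0.37) and P4HA2 (0.36). In the same list 3 fell, DDIT4, ANGPTL4 (-0.93 ± 0.12) and NDRG1 (-0.47 ± 0.12), with 7 and 3 adjusted over the list alone (list adjusted p = 0.227). Of 17 glucocorticoid and progestin targets 3 rose, SGK1, HSD11B2 (0.51) and MT2A (0.43). SGK1 had a mean of 2.93 in the vehicle arrays, near the background probe sets with medians of 2.71 to 2.84, and 3.85 in the E2 arrays, so no size of its rise is given. There 4 fell, ELF5 (-0.45 ± 0.05), TSC22D3 (-0.61 ± 0.10), EDN1 (-0.27 ± 0.04) and NFKBIA, with 4 and 5 adjusted over the list alone (list adjusted p = 0.385). Of 11 androgen targets ACP3 and NDRG1 fell and 0 rose, ACP3 from 4.42 to 3.68, near background, with 3 falls adjusted over the list alone (list adjusted p = 0.0504). This list passed without a trend in the prior (adjusted p = 0.0171), without E2 replicate 2 (adjusted p = 0.0461), with the linear offset (adjusted p = 0.0473), with array weights (adjusted p = 0.0489) with the mean of a gene's probe sets (adjusted p = 0.0475) and by fry (adjusted p = 0.00241). Of 17 genes of the aryl hydrocarbon receptor and xenobiotic metabolism TIPARP (1.11 ± 0.06) rose, and the related CYP1A1 (-0.76 ± 0.11) and CYP1A2 (-0.76 ± 0.14), between which shared signal was not tested, fell. Adjusted over that list alone there were 2 rises and 2 falls (list adjusted p = 0.741). OAS2 (-0.51 ± 0.09) was the 1 of 25 interferon genes that fell, and NFKBIA (-0.32 ± 0.07), the inhibitor of NF-κB, the 1 of 20 inflammatory genes. Of these 0 rose in either list, and the same counts held adjusted over each list alone (list adjusted p = 0.697 and 0.892). Calls ended for KCNF1 with any array left out and for CALCR and NDRG1 with any other than E2 replicate 1. They ended for ADM and P4HA2 with any other than vehicle replicate 1, and for CACNA1D without vehicle replicate 2. They also ended for CA12 without E2 replicate 1 or 2, for HSD11B2 without E2 replicate 2 or 3, and for NFKBIA without vehicle replicate 2 or 3 or E2 replicate 1 or 2 (adjusted p up to 0.149 over all these). With array position as a covariate the calls of RXRA, GATA3, KCNF1, CALCR, CACNA1D, ADM, CA12, P4HA2, NDRG1, HSD11B2, MT2A, TSC22D3, EDN1, ACP3, CYP1A2, OAS2 and NFKBIA ended (adjusted p = 0.0572 to 0.433), and among the arrays of position 5 also those of SGK1 and ANGPTL4 (adjusted p = 0.0842 and 0.0788). RXRA, GATA3, KCNF1, CACNA1D, P4HA2, CA12, NDRG1, HSD11B2, EDN1 and NFKBIA lost theirs without a trend (adjusted p = 0.0535 to 0.167).

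Markers of cell identity did not shift as lists by limma camera, while by fry the luminal list (adjusted p = 0.0245) and the immune and endothelial list (adjusted p = 0.0106) did. Without the dimmest genes the immune and endothelial mean went from 0.0993 to -0.0233 (camera adjusted p = 0.801). Its upward mean thus depended on genes of low signal, and fry was not run without them. Of 19 luminal markers 3 rose, AGR3 by 0.77 ± 0.08 (log2 ± SE, n = 3 in each group), TFF3 by 0.33 ± 0.08 and XBP1 by 0.30 ± 0.05, and 3 fell, ELF3 with -0.55 ± 0.13, SPDEF with -0.30 ± 0.05 and GATA3 with -0.23 ± 0.04 (list adjusted p = 0.741). Adjusted over the list alone 6 rose and 3 fell. Of 11 basal and myoepithelial markers the cadherin CDH3 changed by -0.31 ± 0.05 and 10 did not pass, with 3 falls adjusted over the list alone (list adjusted p = 0.362). Of 17 fibroblast and mesenchymal markers fibronectin, FN1, changed by -0.34 ± 0.09 and 16 did not pass, with 1 fall adjusted over the list alone (list adjusted p = 0.607), and their median of 0.00 and mean of -0.04 differ in sign. Of 15 immune and endothelial markers 0 passed by limma over all genes or adjusted over the list alone (list adjusted p = 0.186). Those with the smallest p, CD34 and KDR, measured 2.99 with vehicle, near background, and 3.72 with E2 (adjusted p = 0.0692), and 4.44 with vehicle and 3.89 with E2, near background (adjusted p = 0.095). The calls of TFF3 and FN1 ended with any array left out and that of ELF3 without vehicle replicate 2 or 3 or E2 replicate 1 or 3 (adjusted p up to 0.143). AGR3 alone of the genes named here kept its call with array position as a covariate (adjusted p of the others that had passed 0.0523 to 0.165) and without a trend (0.0831 to 0.158). Over the 37 lists, 15 shifted, 10 up and 5 down, 8 of them with an estimated correlation. For the mitochondrial biogenesis, antiproliferative and immediate early lists the estimate (0.00499, 0.0044 and 0.001) lay under the preset 0.01. Their calls were thus not lost to a higher correlation. For fatty acid oxidation, amino acid transporters, tRNA synthetases and G2/M genes the estimate lay above it (0.0756, 0.0583, 0.124 and 0.0253).

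**Figure D4:**
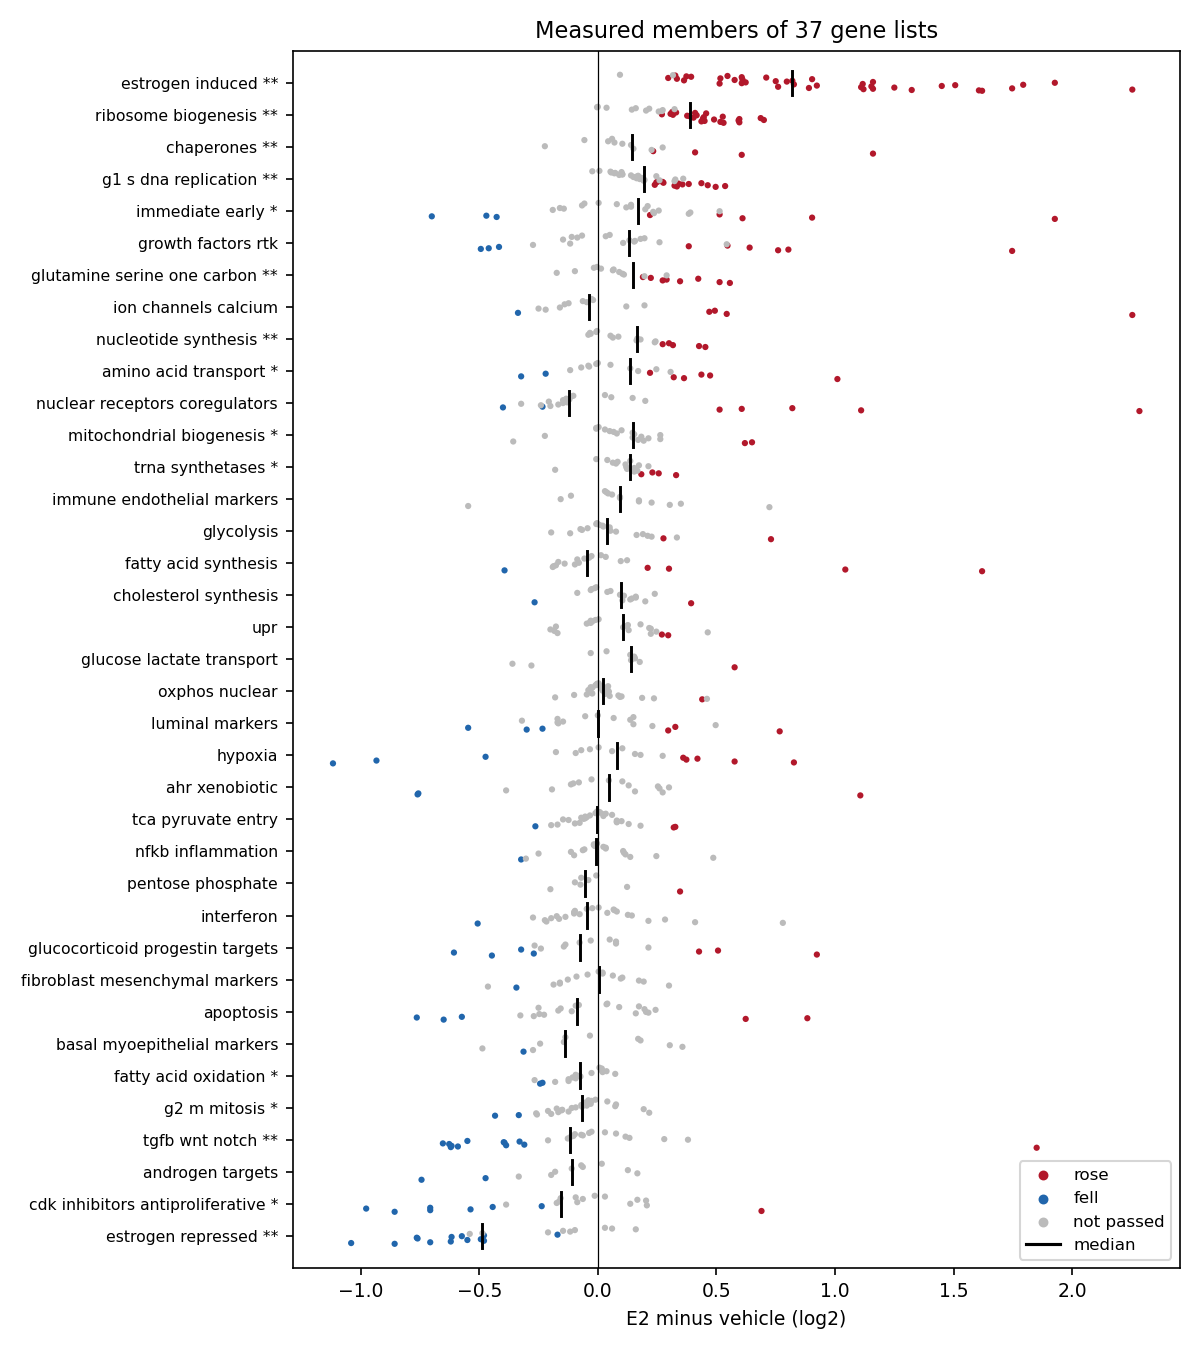
Change of each measured member (point; E2 minus vehicle, log2, horizontal axis) of the 37 lists (rows, ordered by mean change), red where it rose, blue where it fell and grey where it did not pass; black bars are list medians and the vertical offset of points has no meaning. One asterisk marks the 15 lists that shifted and 2 asterisks the 8 of them that also did with an estimated correlation, from the estrogen-induced list with a median of 0.82 to the estrogen-repressed list with a median of -0.49.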

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

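The tests on array position, in the form given here, and the splits of the arrays were chosen after the results were seen.

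Among the 27709 unnamed probe sets, which the comparison of genes does not use, 7 passed the same test for E2 against vehicle, 5 higher and 2 lower, with 1662 at an unadjusted p under 0.05 (6% of them). Among 1852 probe sets that stand for several genes 35 passed, 22 higher and 13 lower. Both were noted because they are signals outside the main measurement. The unnamed probe sets with the smallest p in each direction were 16967863, with a log2 change of 1.33 ± 0.08 (SE; adjusted p = 0.0103), and 16676150, with -1.64 ± 0.12 (adjusted p = 0.0131).

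E2 replicate 1 lay apart from E2 replicates 2 and 3 on the second principal component, and the number in its array name, assumed to be a position, is 5 as in the vehicle arrays. Position argued poorly for the E2 calls themselves. In genes called from E2 replicates 2 and 3 and 2 vehicle arrays, the change of E2 replicate 1 over the vehicle array kept aside had a median ratio to the called change of 0.841, 0.897 and 0.839 for vehicle replicates 1, 2 and 3, where position as the whole cause needs a ratio near 0, and 94.5% to 97.4% of genes kept their sign. Whether position sets E2 replicate 1 apart cannot be told apart from a culture that differed, since it is the only E2 array at position 5. Its difference from the other E2 arrays had r = 0.019 with the mean E2 effect across genes, but the correlation first written, with the effect of the other E2 arrays alone, was -0.319 and so past the bound of 0.3 set beforehand for a stronger or weaker response. That form was set aside after its result was seen, because E2 replicates 2 and 3 treated alike gave -0.335 and -0.304, as terms that share arrays do.

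The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1405 genes, 418 genes of at least 1.5-fold and 15 lists, and the highest of the other splits gave 0 genes, 0 such genes and 5 lists. In each of these comparisons the real split was the 1 split with as large a result. Every other split mixes E2 and vehicle arrays in both of its groups, so an E2 effect widens the spread within them. The other splits therefore do not show how many genes or lists would pass without an effect.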

How the results depend on the processing

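Array position, as a covariate or by keeping only position 5, was chosen after seeing the data. The 1405 genes, 752 higher and 653 lower, became 578 without a trend (346 and 232), 524 with position as a covariate (315 and 209) and 352 on the 4 arrays of position 5 (217 and 135), of which 571, 454 and 308 were among the 1405. Fewer arrays or degrees of freedom enter the latter pair of fits, and in both the E2 effect comes from E2 replicate 1 alone. Lost calls there do not show an effect of position. The median ratio of the 1405 fold changes to those first obtained was 0.992 in both, which is partly built in, since the same arrays had served to call these genes. With equal medians 1421 passed (687 and 734), so that falls then outnumbered rises. The 418 genes of at least 1.5-fold became 220 with the linear offset (150 higher, 70 lower), which shrinks changes of dim genes by construction, and 267 at position 5 (90 lower). With 1 array left out, 892 to 1081 genes passed (496 to 592 higher, 392 to 489 lower), 366 to 409 of at least 1.5-fold (229 to 257 higher, 137 to 162 lower) and 15 to 16 lists. The lowest count came without E2 replicate 3 (892, with 496 and 396), then without vehicle replicate 2 (906), and 496 rose without E2 replicate 2. Lists shifted numbered 8 with an estimated correlation and 24 by fry, which does not set a list against other genes.

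No pairing by replicate number was visible, with deviations of same-numbered arrays correlated at -0.038, 0.022 and -0.0091. This does not exclude that same-numbered cultures were set up together. With the number as a block 1185 genes passed, 1117 of them among the 1405, with 15 lists. Among 163 named genes past the threshold, calls were kept by 97 without a trend, 86 with position as a covariate, 74 at position 5, 143 with the block and at least 123 with any array left out, and in each of the other settings by at least 156; 0 reversed. Of the 15 lists 7 lost their call with an estimated correlation. Among these, fatty acid oxidation and immediate early genes also lost it in the other settings given with them. In lists that had not passed, the direction of the test turned as follows; the cause was not tested. For pyruvate entry and the TCA cycle the mean was -0.0149 with equal medians, -0.000287 without vehicle replicate 1, -0.00322 without vehicle replicate 3, -0.00247 without E2 replicate 3 and 0.00322 at position 5 (up to 0.00868 with other arrays left out). For the interferon list it was 0.0491 with the covariate and at position 5, and for xenobiotic genes -0.0544 without dim genes. For nuclear receptors it was 0.135 with the block and 0.103 to 0.159 with 1 array left out, turned without E2 replicate 1. For fatty acid synthesis the range was 0.0631 to 0.11 and for inflammatory genes -0.0177 to 0.0113, both turned without vehicle replicate 3. For the pentose phosphate list it was -0.0194 to 0.0142, turned at 0.000625 without E2 replicate 1, and -0.00208 by fry. The mean alone changed sign, with the test keeping its direction, in 23 further cases over 8 lists, none of which had passed. The turned means were at most 0.0233 in size. That largest one was of the immune and endothelial markers, which went from 0.0993 to -0.0233 without dim genes. Also among these cases were hypoxia (-0.00694 without E2 replicate 1), glucocorticoid targets (0.0112 with the covariate and at position 5), interferon (0.00247, 0.00487 and 0.0215 without vehicle replicate 1, vehicle replicate 3 and E2 replicate 3) and xenobiotic genes (-0.00108 and -0.00951 without vehicle replicate 3 and E2 replicate 1). The other table holds the same values and tests nothing. Background probe sets had medians of 2.71 to 2.84, and signal near that level leaves little room to see a fall in dim genes.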

Other observations

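All genes and families in the first paragraphs, and the families themselves, were chosen after the values were seen; so was the count of small nucleolar RNA genes that rose in hosts that rose.

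Several receptors and channels outside the named sets rose. The neuropeptide Y receptors NPY1R and NPY5R rose by 1.75 ± 0.08 and 1.38 ± 0.11 (log2 ± SE, n = 3 arrays in each group; adjusted p = 9.53e-07 and 6.12e-05, limma). Beside KCNK5, the potassium channels KCNH1, KCNQ5 and KCNK15 rose by 1.49 ± 0.07, 1.23 ± 0.14 and 0.94 ± 0.14, and of 84 potassium channel genes 6 rose and 1, KCNE2 with -0.69 ± 0.14, fell, without a shift of the family (adjusted p = 0.279). The KCNE2 call ended without vehicle replicate 1 or 3 or E2 replicate 3 and with array position as a covariate (adjusted p = 0.156), and the KCNK15 call among the arrays of position 5 (adjusted p = 0.051); that of KCNE2 also ended without a trend (adjusted p = 0.0509).

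Of 40 families formed by symbol, 8 shifted by limma camera, and 0 did with an estimated correlation (lowest adjusted p = 0.362). RNA polymerase subunits shifted up (adjusted p = 0.00105), with 7 of 30 higher and 0 lower, among them POLR3G, of RNA polymerase III, by 0.69 ± 0.07. Of the 7, 5 lie outside the lists fixed in advance. The 7 became 5 without vehicle replicate 1, 4 without any other array but E2 replicate 3, 3 without that one, and 2 with array position as a covariate, at position 5 or without a trend, where POLR3G kept its call. WD repeat genes (10 of 56 higher, 7 of them outside the lists; adjusted p = 0.0408), among them WDR4 with 0.63 ± 0.10 and WDR3 with 0.43 ± 0.06, and DEAD-box helicases (5 of 34 higher, 3 outside the lists; adjusted p = 0.00195) also shifted up. The 10 WD repeat genes became 6 without vehicle replicate 1, E2 replicate 1 or E2 replicate 3, 4 with position as a covariate or without a trend and 0 at position 5, and the 5 helicases became 3 without vehicle replicate 2 or without a trend, 2 without any other array or with the covariate, and 0 at position 5. Mitochondrial ribosomal proteins shifted up by a median of 0.08 with 3 of 71 higher, MRPS23, MRPL15 and MRPL17 (adjusted p = 0.00145), and cytosolic ribosomal proteins, by a median of 0.07 with 1 of 55 higher (adjusted p = 0.00962), which became 0 without vehicle replicate 1 or 2 or E2 replicate 1 or 3, with position as a covariate, at position 5 or without a trend, and 2 without vehicle replicate 3 or E2 replicate 2. Protocadherins shifted down (adjusted p = 0.00195), with 5 of 27 lower and 0 higher (1 lower with position as a covariate, at position 5 or without a trend), PCDH7 from 4.45 to 3.64, near background, PCDHB4 with -0.67 ± 0.13, PCDH1 with -0.56 ± 0.11, PCDH10 with -0.39 ± 0.09 and PCDHB14 with -0.36 ± 0.08. The PCDHB genes are related copies between which shared signal was not tested, and each of the 5 calls ended with at least 1 array left out, PCDH1 without vehicle replicate 2 only (adjusted p = 0.0618). The 5 falls became 1 without vehicle replicate 1, vehicle replicate 3 or E2 replicate 3, and 2 without E2 replicate 2. They became 3 without vehicle replicate 2 and 4 without E2 replicate 1. Leaving out 1 array also ended the calls of MRPL15 and MRPL17 (adjusted p up to 0.0874). With array position as a covariate the calls of WDR4, MRPL15, MRPL17 and the protocadherins other than PCDH1 ended (adjusted p = 0.0531 to 0.284), and among the arrays of position 5 also that of WDR3 (adjusted p = 0.0671). Without a trend in the prior those of MRPS23, MRPL15, MRPL17 and the protocadherins other than PCDH10 ended (adjusted p = 0.055 to 0.167).

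Genes that neighbour each other rose together more often than chance placement gives. Among 15463 adjacent, non-overlapping pairs of protein-coding genes both rose in 51 pairs, against a mean of 26.6 and a highest value of 48 in 10000 permutations of the calls within levels of signal (p = 1e-04, the smallest they can give), and both fell in 41 against a mean of 21.5 (p = 2e-04). Signal shared between neighbours whose symbols share their first 3 letters was argued against as the whole cause. Without such pairs both still rose in 48 pairs against a mean of 25.5 (permutation p = 1e-04). That rule took out IL20 with IL24 but kept the related IL19 with IL20, so signal shared by related genes with other symbols was not tested. Pairs among the 51 were IL20 with IL24, SLC7A2 with PDGFRL and RASGRP1 with THBS1. Regulatory elements shared by neighbours and transcripts that run on into the next gene were not tested and stay open.

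Of 217 small nucleolar RNA (snoRNA) genes 10 rose and 1 fell, and the shift of the 215 among them named by symbol (adjusted p = 0.0195) was lost with an estimated correlation (adjusted p = 0.362). The rises and falls by symbol became 6 and 2 without E2 replicate 1, 4 and 1 without E2 replicate 3, 5 and 0 without vehicle replicate 2, 3 and 1 with array position as a covariate, 2 and 1 at position 5 and 3 and 0 without a trend, so the pattern is weak. Of the 10 rises 5 lay in measured hosts, which changed by -0.117 to 0.0867 and did not pass, so no rise of the host was found for these. The other 5 had no measured host, so hosts that rose as the cause of those could not be examined. That 0 of the 10 lay among the 8 snoRNA genes in hosts that rose says little with so few genes. A part played by hosts cannot be told apart from chance with 8 genes (one-sided permutation p = 0.222, where 0.05 or more had been set beforehand to count against hosts). Uneven recovery of short RNA between extractions cannot be told apart from other causes, since the test set for it, on genes outside hosts that rose, held 209 of the same 217 genes and so gave the median of all of them, 0.0733. Mean signal over these genes was 4.66, 4.69 and 4.74 on the vehicle arrays and 4.76, 4.72 and 4.81 on the E2 arrays, so the groups overlap.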
